A study of Mus musculus with 4 samples.

How the data were processed

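Total RNA of small-intestinal epithelial cells, in 2 samples from WT and 2 from IKKb(EE)IEC mice, was labelled with Cy3 as cRNA from 250 ng RNA, per the labels' protocols, and each sample was hybridised to 1 array. The arrays are of Agilent design 014868 and carried 43379 non-control spots for 41174 probes and 1639 control spots each. The series' design text states biological replicates, the number of mice behind a sample is not given in the sources used here, and the group and replicate number of each array come from the sample titles. All 4 arrays lie on 1 slide and were scanned together, per the file headers, with the WT samples at positions 1 and 2 and the IKKb(EE)IEC samples at positions 3 and 4. No slide or scan block can therefore be fitted, and position on the slide and genotype cannot be told apart.

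The deposited spot intensities come from Agilent Feature Extraction 9.5.3.1, per the file headers, as a background-subtracted and spatially detrended processed signal in which dim spots carry a substituted value. The headers record no normalization between arrays. The authors' value table of 40913 probes is also deposited as linear intensities. Its columns followed the median spot intensity of the same array with a Spearman correlation of 0.999 to 1.00 across probes and had medians of 111.5 to 112.0, so it was normalized between arrays by a method not given in the sources used here. The remaining columns used, which the file headers define, are flags of the spots. The 75th percentile of the processed signal was 60.3 and 66.1 on the WT arrays and 94.6 and 107.8 on the IKKb(EE)IEC arrays, and the median local background was 29 to 31. Arrays give no counts, so precision is limited by the number of arrays and, for dim probes, by the background.

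Log2 of the processed signal was shifted by each array's 75th percentile over non-control spots. Control spots and non-uniformity outliers (1 to 7 spots per array) were left out, saturated spots (2 to 4 per array, among them 1 spot of Fabp2 on 1 array) were kept, and spots of a probe were averaged. A probe entered where it was well above background on at least 2 of the 4 arrays, which left 16405 probes. A gene was represented by the probe with the highest mean, which gave 12446 genes, 3160 of them with over 1 such probe. Of 406 called genes with over 1 probe, 74 had a probe of opposite sign. Gene names follow a table of the GRCm38.p6 assembly for 24367 probes matched through RefSeq accessions, which changed the name of 4781. A further 977 took the name given to another probe of the same listed name, and 15830 kept the name in the files. Coordinates are those of the files (mm8) and mark the probe. The exon it lies in is not given in the sources used here.

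Genotypes were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3 (two-sided, Benjamini-Hochberg over the genes tested, adjusted p below 0.05). The prior had 3.51 degrees of freedom and a standard deviation of 0.202. Standard errors are moderated by this fit. With 2 against 2 arrays, 3 splits exist, so no permutation can reach a p below 0.05, since each split makes up 33.3%. For a single gene, a random split separates the groups fully with a chance of 33.3%, and 69.1% of the genes were separated (3520 higher and 5085 lower). Genes share the shifts of their arrays, so setting these shares side by side does not test for an effect of genotype. Where a probe was not well above background on either array of a genotype, the fold is given as at least N-fold. It sets the mean of the brighter genotype against the mean, over the arrays of the dimmer one, of the higher of the probe's own value and the lowest normalized value of any probe well above background. Where the probe's own values are the higher ones, the figure equals the measured fold, as for Epop (32.6-fold). It varies with the arrays used and is called a bound in this sense only, not as a strict limit.

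The text names Ikbkb, the 12 largest rises and 12 largest falls among genes past the threshold whose arrays separate fully by genotype, leaving out clone, Riken, LOC, Gm-number and accession names, and from each gene list up to 4 passing members with the largest change, or up to 2 with the smallest p where none passed. Genes named beyond this rule, such as Cd74, Ciita, Lgr5, Olfm4, Muc2, Reg3g, C1qb, Lyz2, Il33, Cyp3a11 and Tap2, were chosen after their values were seen. One gene that the rule takes is not reported here. The rule, 31 gene lists, the tests and all alternatives but 1 were fixed before the data were examined. The lists cover NF-kB feedback, chemokines, antimicrobial genes, Paneth and T cell markers as main lists, and other cell types, intestinal segments, metabolism, stress, clock and sex as secondary ones. The 30 lists with at least 5 measured members were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over these lists. Camera called 8 lists. With an estimated correlation it called 0, the lowest adjusted p being 0.726, and fry called 1, the NF-kB list. Fabp1 is in 2 lists. Gene plots show values as fitted or measured, also where a genotype gives only a bound.

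The code was tested on simulated data for the same comparison of 12446 genes, with spreads drawn from the fitted prior and 200 genes changed. Of genes changed 2-fold, 4-fold and 8-fold, 5.97%, 79.1% and 97.0% were recovered, and 8 of 12246 unchanged genes were called. Fewer genes were changed here than the 992 higher and 892 lower genes called in the data. The Benjamini-Hochberg adjustment depends on that number, so these shares do not give the power of the real comparison. A simulated shift of 1 log2 unit in 1 list of 30 genes gave an adjusted p by camera of 4.01e-32 with the preset correlation and 0.173 with an estimated correlation, and 0 of the 29 other lists were called. Noise was drawn independently for each gene. The simulation therefore does not show how often the preset correlation gives false calls where genes are correlated, as in the Paneth list (estimated at 0.46). The alternatives were normexp background correction (offset 50), quantile normalization, a percentile over detected probes, a median shift, the authors' value table, no filter, a stricter filter, the mean over probes, a trended robust variance, leaving out each array, a replicate block, other thresholds and single probes. One, a repaired normexp fit, was added after seeing the data. Python 3.11.15 with pandas 2.3.3 read the files, and matplotlib 3.10.9 drew the figures.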

Results

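The samples were epithelial cells freshly isolated from the small intestine of mice, and total RNA was measured on 1-colour oligonucleotide microarrays. IKKb(EE)IEC mice carry a constitutively active form of the kinase IKKb, which activates the transcription factor NF-kB, in intestinal epithelial cells. Their wild-type (WT) littermates served as controls. Each genotype had 2 biological replicates, on 1 array each, so that the number of arrays limits the precision of every value. The share of spots well above background was 34.3% and 36.0% on the WT arrays and 40.8% and 41.1% on the IKKb(EE)IEC arrays. Over the 12446 genes tested, the 2 WT arrays correlated at 0.978 and the 2 IKKb(EE)IEC arrays at 0.994, against 0.937 to 0.947 between genotypes. The 2 WT arrays were over 4-fold apart for 76 genes and the 2 IKKb(EE)IEC arrays for 3 genes.

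The design asks what constant IKKb activity changes in the transcripts of the intestinal epithelium. In IKKb(EE)IEC, 20 of 30 measured interferon-responsive genes, 12 of 23 genes of the NF-kB pathway and its feedback, 11 of 24 genes of sterol and fatty acid synthesis, 10 of 19 markers of macrophages and dendritic cells and 9 of 25 chemokines and cytokines rose. Paneth cell markers fell in 10 of 11 cases and genes of xenobiotic metabolism in 10 of 30, and 2 of 25 junction and keratin genes rose. These were the 8 lists that passed with the preset correlation, and the values do not tell which of the isolated cells a transcript came from. Over all genes tested, 15.1% were called in either direction, so the count of 2 of 25 does not by itself set the junction and keratin list apart. With an estimated correlation between genes, no gene list passed its test, the lowest adjusted p being 0.726, a value that these 8 lists share after adjustment. In the simulation that test also missed a shift of 1 log2 unit in a list of 30 genes (adjusted p by camera = 0.173). Not passing it therefore does not show that a list is unchanged. Of the 12446 genes, 992 were higher and 892 lower in IKKb(EE)IEC at an adjusted p below 0.05 in limma, and 727 and 442 of these differed by at least 2-fold. In 354 of the genes that were higher, the probe was not well above background on either WT array, and in 77 of the genes that were lower, on neither IKKb(EE)IEC array. The lowest normalized log2 value well above background was -2.84 and -2.62 on the WT arrays and -3.77 and -3.83 on the IKKb(EE)IEC arrays. A probe at the same level thus fell below background more readily in WT, and these counts cannot be set against each other. Higher genes made up 52.7% of the calls, a share that became 63.2% with a shift by the array median and 72.0% with a repaired normexp background correction. It was 42.6% and 45.8% without WT replicate 1 and 2, and with a filter on probes well above background on all arrays 771 genes were higher and 1157 lower. The counts depended on which array was left out. They were 2628 higher and 3534 lower without WT replicate 1 and 1911 and 2262 without WT replicate 2. They were 165 and 82 without IKKb(EE)IEC replicate 1 and 225 and 105 without IKKb(EE)IEC replicate 2. Of the 105 genes taken by the fixed naming rule, 60 no longer passed without IKKb(EE)IEC replicate 1 and 54 without replicate 2, and none changed sign under any alternative. Both arrays were needed for Ubd, Reg4, Ms4a7, Ahr, Hmgcs1, Srebf2, H2-Eb1, Ripk3 and Mlkl to pass, and IKKb(EE)IEC replicate 1 for C3, Ang4, H2-Ab1, Scd2 and Cyp1a1. All 105 genes taken by the naming rule separated fully by genotype, so leaving out 1 array could not change their sign. The median log2 fold change of all genes was -0.12, and lay between -0.08 and -0.02 under the other scalings of the same arrays, so small shifts of gene lists are to be read against it. All log2 fold changes are IKKb(EE)IEC minus WT, with the standard error (SE) of the limma fit and n = 2 arrays per genotype.

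Ikbkb, the gene of the activated kinase, was represented by 1 probe on chromosome 8 (24125327 to 24125386, mm8). It was well above background on all 4 arrays, at -0.72 and -0.27 in WT and 0.33 and 0.34 in IKKb(EE)IEC (normalized log2 signal). The log2 fold change of 0.83 ± 0.21 missed the threshold, with an adjusted p of 0.0551. It was 0.20 with the normexp correction, 0.31 with its repaired form and 0.30 in the authors' value table (adjusted p = 1.00, 0.113 and 0.0989). The sources used here do not say whether this probe lies in the transgene, so the value checks the labels in part at most.

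Ccl20, the chemokine that attracts CCR6-bearing leukocytes, rose by 7.14 ± 0.32 (adjusted p = 0.000892, chromosome 1, 82997949 to 82998008, mm8). Ubd, a ubiquitin-like modifier, rose by 5.52 ± 0.91 (adjusted p = 0.0224), with values of 4.04 and 7.01 without WT replicate 1 and 2. The adhesion molecule Icam1 rose by 5.18 ± 0.17 (adjusted p = 0.000641). Several probes were not well above background on either WT array, so that their rises are given as at least N-fold, which is not a strict limit. These were at least 129.9-fold for Csf1, the growth factor of macrophages (adjusted p = 0.000275), at least 169-fold for the BAFF receptor gene Tnfrsf13c (adjusted p = 0.000641) and at least 174-fold for Xlr5a (adjusted p = 0.000312). Rps6kl1 was at least 117-fold higher and Dlk1 at least 31.6-fold, with at least 2.98-fold for a second Dlk1 probe. Epop, C1qc and Pf4 were at least 32.6-fold, 29.7-fold and 30.9-fold higher, where the bound for C1qc was 16.9-fold and 52.1-fold without WT replicate 1 and 2. Among these rises Dlk1 alone had over 1 probe that passed the filter, so the others rest on single probes.

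The largest fall among the named genes was that of Mbl2, a mannose-binding lectin, whose signal was at least 679-fold lower in IKKb(EE)IEC (adjusted p = 0.00276, chromosome 19, 30305551 to 30305610, mm8). Without WT replicate 1 and 2 this bound was 338-fold and 1361-fold. Rdh16f2 was at least 36.1-fold lower and Retnlb, a goblet cell product, at least 26.7-fold (adjusted p = 0.00218 and 0.0378), a bound that was 8.73-fold and 81.7-fold for Retnlb without WT replicate 1 and 2. Cd36, a fatty acid transporter, fell by 4.18 ± 0.20 (adjusted p = 0.000892), Zfp423 by 4.05 ± 0.17, Clps by 4.01 ± 0.43, Bst1 by 3.97 ± 0.25 and Farsa by 3.84 ± 0.17. The falls of Gsdmc (-4.12 ± 0.82) and Aqp7 (-3.88 ± 0.71) carried larger errors, and the 2 WT arrays differed by -2.66 and -2.27 (replicate 2 minus replicate 1). Without WT replicate 1 and 2 the values were -2.79 and -5.45 for Gsdmc, -2.75 and -5.02 for Aqp7 and -3.39 and -4.64 for Clps. Mup1 and Mup5, major urinary proteins made mainly by liver, were at least 26.7-fold and 22.9-fold lower. The liver transcripts Alb, Ahsg, Fgb and Apoh were well above background on the array of WT replicate 2 alone. Without that array Mup1 and Mup5 were at least 8.32-fold and 7.61-fold lower, and without WT replicate 1 at least 85.9-fold and 68.9-fold. Mup1, Mup5, Retnlb, Gsdmc and Aqp7 no longer passed when either IKKb(EE)IEC array was left out. Icam1, Cxcl11, Nos2, Ms4a7, Ahr, Cd44 and Onecut2 were well above background on 1 of the 2 WT arrays, and Cd36, Ccne2 and H2-DMb2 on 1 of the 2 IKKb(EE)IEC arrays.

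Many genes of the NF-kB pathway and its feedback rose. Of 23 measured members, 12 rose, none fell and 11 did not pass, and adjusted over the list alone 16 rose. Nfkbie and Nfkbia, which encode inhibitors that hold NF-kB in the cytoplasm, rose by 3.61 ± 0.18 and 2.61 ± 0.30 (adjusted p = 0.000997 and 0.00778). Tnfaip3, the ubiquitin-editing enzyme A20, rose by 2.76 ± 0.24 (adjusted p = 0.00384), and Map3k14, the kinase of the non-canonical branch, was at least 5.75-fold higher. Nfkb2, Bcl3, Tnip1, Birc3 and Relb rose by 1.92 to 2.25. The members Traf1, Chuk and Birc2 had values of 0.03, -0.16 and 0.13. The median of the list was 1.45 and its adjusted p by camera, with a preset correlation of 0.01, was 1.07e-09. The adjusted p was 0.726 with an estimated correlation, and 0.0399 by fry.

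Chemokines and cytokines moved in both directions. Of 25 measured members, 9 rose, 3 fell and 13 did not pass, and adjusted over the list alone 13 rose and 4 fell. Beside Csf1 and Ccl20, genes for ligands of the receptor CXCR3 rose. Cxcl11 rose by 4.31 ± 0.20 (adjusted p = 0.000892), and Cxcl10 was at least 37.05-fold higher. The chemokine gene Cxcl16 rose by 3.82 ± 0.16 and the cytokine gene Ltb by 3.93 ± 0.31. The 3 that fell were Il33 (-2.86 ± 0.33), Il18 (-2.05 ± 0.27) and Ccl6 (-1.41 ± 0.23). The median was 0.73, with an adjusted p by camera of 0.000924 and an adjusted p of 0.726 with an estimated correlation. Among the 18 members well above background on all arrays, the median was -0.03 and the list did not pass (adjusted p = 0.172).

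**Figure D1:**
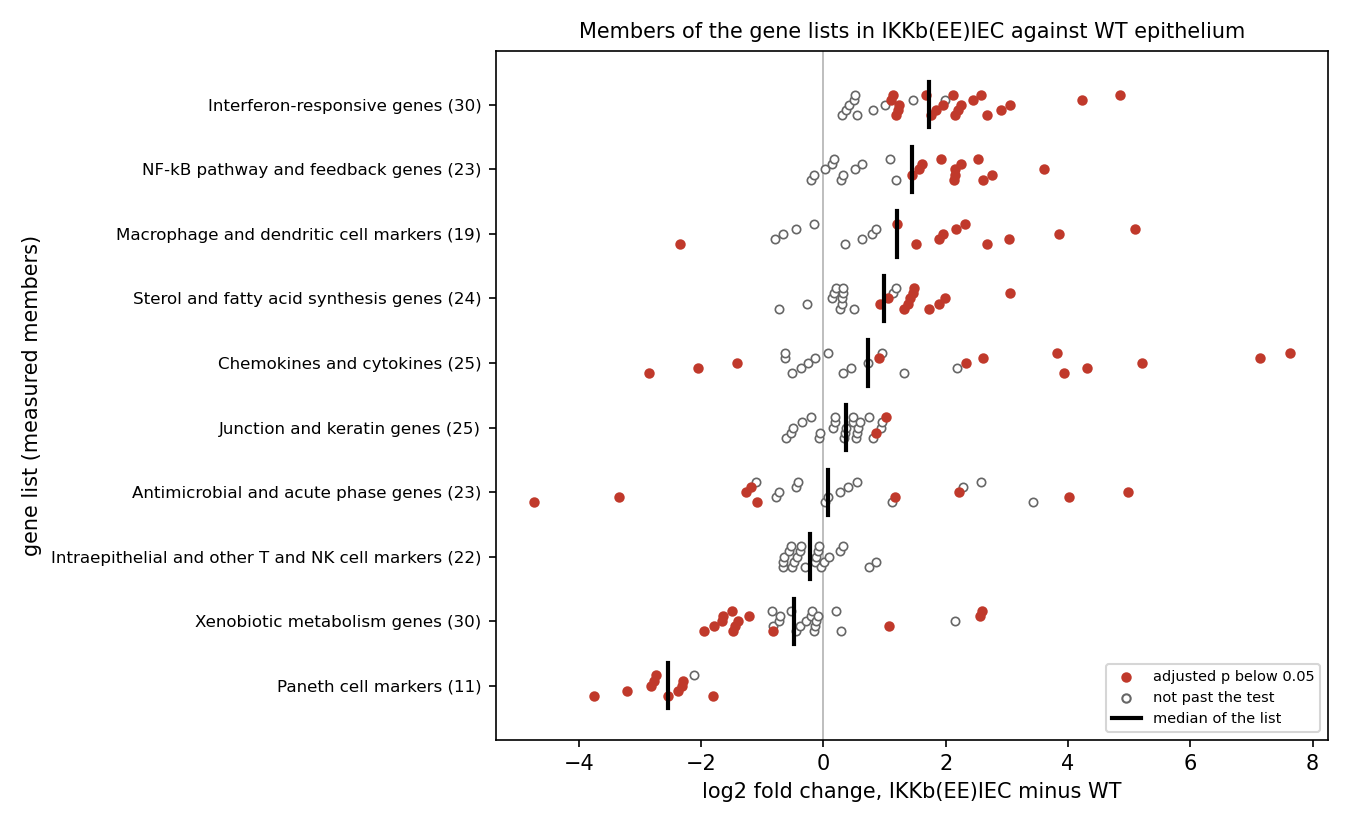
Log2 fold change (IKKb(EE)IEC minus WT, x axis) of each measured member of 10 gene lists (y axis, number of measured members in brackets). Filled points passed the gene test, open points did not, and black bars are list medians, from -2.55 for the Paneth cell markers to 1.72 for the interferon-responsive genes.

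Antimicrobial and acute phase genes showed no common direction. Of 23 measured members, 4 rose, 5 fell and 14 did not pass, and adjusted over the list alone 5 rose and 6 fell. C3, the central complement component, rose by 4.98 ± 0.74 (adjusted p = 0.0170), and Nos2, the inducible nitric oxide synthase, by 4.01 ± 0.42 (adjusted p = 0.00641). Without WT replicate 1 and 2 the values were 3.80 and 6.16 for C3, 3.37 and 4.66 for Nos2 and -2.31 and -4.38 for Reg4. Tlr2 and Dmbt1 also rose, by 2.22 ± 0.32 and 1.17 ± 0.26. Beside Retnlb, the falls were those of Reg4 (-3.34 ± 0.66), Reg1 (-1.27 ± 0.17), Reg3a (-1.18 ± 0.28) and Ido1 (-1.08 ± 0.19). The bactericidal lectin gene Reg3g had a value of 1.12 ± 0.99 and Reg3b of -0.44 ± 0.78, and their 2 WT arrays differed by 3.26 and 2.54. The list had a median of 0.07 and did not pass (adjusted p by camera = 0.592).

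Paneth cells, the secretory cells at the base of the crypt, had lower marker transcripts in IKKb(EE)IEC. Of 11 measured markers, 10 fell, none rose and Defa21 did not pass (-2.12 ± 0.69, adjusted p = 0.0879), while adjusted over the list alone all 11 fell. Lyz1, the Paneth lysozyme, fell by 2.74 ± 0.43 (adjusted p = 0.0193) and Mmp7, which activates defensins, by 1.81 ± 0.25 (adjusted p = 0.0135). The alpha-defensins Defa1 and Defa22 fell by 2.77 ± 0.26 and 2.81 ± 0.23 (adjusted p = 0.00467 and 0.00349), and Ang4 and Itln1 by 3.76 ± 0.58 and 3.21 ± 0.27. Without WT replicate 1 and 2 the values were -3.38 and -2.11 for Lyz1, -2.90 and -4.62 for Ang4 and -3.21 and -1.04 for Defa21. Alpha-defensin genes are close copies of one another, so their probes may share signal and are not independent. The median was -2.55, with an adjusted p by camera of 4.86e-08 and an adjusted p of 0.726 with an estimated correlation. In the same samples the distal small intestine list had a median of -0.41, with -0.77 and -0.06 without WT replicate 1 and 2, and the stem cell and Wnt target list of -0.11.

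Lists of other epithelial lineages did not pass. Among goblet cell markers 3 of 15 fell, with Spink4 at -1.63 ± 0.24, Klk1 at -1.28 ± 0.24 and Tpsg1 at -0.91, and none rose (median -0.55, adjusted p by camera = 0.127), and the list passed with the unrepaired normexp correction (adjusted p = 0.04995). The goblet mucin gene Muc2 had a value of 0.28 ± 0.22. Enteroendocrine markers had 2 falls among 21, the neurotensin gene Nts at -1.27 ± 0.19 and Fev at -0.76 (median -0.40, adjusted p = 0.194). Tuft cell markers had 2 falls among 14, Ltc4s and Tas1r3 (median -0.65, adjusted p = 0.254), and passed without WT replicate 2 (median -1.05, adjusted p = 0.000493). In the stem cell and Wnt target list, Cd44 rose by 1.83 ± 0.38 and Sp5 fell by 1.26 ± 0.25, and the other 18 measured members did not pass, among them Lgr5 (-0.23 ± 0.29) and Olfm4 (-0.45 ± 0.25). Its test gave an adjusted p of 0.955, with a direction opposite in sign to the median. Of 30 cell cycle genes, Plk1 rose by 0.71 ± 0.17, Ccne2 fell by 1.28 ± 0.21 and 28 did not pass (median 0.12, adjusted p = 0.142), and the list passed without WT replicate 2 and without a filter (adjusted p = 0.0280 and 0.000210). Among 32 absorptive enterocyte genes 2 rose and 6 fell (median -0.19, adjusted p = 0.592). The alanyl aminopeptidase gene Anpep rose by 1.10 ± 0.16. The fatty acid-binding protein genes Fabp2 and Fabp1 fell by 1.56 ± 0.23 and 1.35 ± 0.28 and the lactase gene Lct by 1.26. The probe of Fabp2 was saturated on 1 array, and a second probe without saturation gave -1.82 ± 0.25. Fabp2 and Fabp1 had values of -0.32 and -0.51 and did not pass after quantile normalization. Adjusted over the list alone, 0 goblet cell markers rose and 4 fell, and the corresponding numbers were 0 and 1 for enteroendocrine, 0 and 2 for tuft cell, 1 and 3 for stem cell, 0 and 1 for cell cycle and 5 and 10 for absorptive genes.

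Several markers of macrophages and dendritic cells rose, and those of T and NK cells did not pass in either direction. In the macrophage and dendritic cell list, 10 of 19 measured members rose, 1 fell and 8 did not pass, and adjusted over the list alone 12 rose and 3 fell. Beside C1qc, the Fc receptor gene Fcgr1 rose by at least 14.5-fold and Adgre1, the macrophage antigen F4/80, by at least 6.38-fold, while Ms4a7 rose by 3.03 ± 0.63. Lyz2, whose sequence is close to that of Lyz1, fell by 2.34 ± 0.45, and C1qb and Csf1r had values of -0.15 ± 0.17 and 0.34 ± 0.32. Without WT replicate 1 and 2 the values were 2.04 and 4.01 for Ms4a7 and -3.04 and -1.65 for Lyz2. The median was 1.20, with an adjusted p by camera of 0.000131 and an adjusted p of 0.726 with an estimated correlation, and the list did not pass over members well above background on all arrays (median 0.10, adjusted p = 0.393). Of 22 markers of intraepithelial and other T and NK cells none passed, with 0 also adjusted over the list alone (median -0.22, adjusted p = 0.366), and the smallest p values belonged to Klrd1 (-0.66 ± 0.18) and Cd3d (-0.65 ± 0.18).

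Lists for further cell types that isolated epithelium could hold did not pass in the limma comparison. B and plasma cell markers had 1 rise (Blnk) and 2 falls (Cr2 and Blk) among 7 (median -0.12, adjusted p = 0.753). Neutrophil and mast cell markers had 1 rise (Mmp9) and 1 fall (Mcpt4) among 7 (median -0.53, adjusted p = 0.328). Stromal and muscle markers had 2 rises, Mylk at 1.95 ± 0.17 and Col4a1 at least 1.72-fold higher, and 2 falls, Fbln1 at -3.53 ± 0.23 and Myh11 at -0.72, among 12 (median -0.26, adjusted p = 0.592). Endothelial and blood markers had 1 rise, Pf4, among 6 (median 0.15, adjusted p = 0.592), and passed with a median shift (adjusted p = 0.0312). Pancreas acinar markers had 2 falls among 8, Clps and Pnliprp2 (median -0.49, adjusted p = 0.127), and passed without WT replicate 2, without IKKb(EE)IEC replicate 1, with a median shift and with the unrepaired normexp correction (adjusted p = 0.0254, 0.0393, 4.69e-05 and 0.0164). Adjusted over the list alone, 1 B cell marker rose and 2 fell, and the corresponding numbers were 1 and 1 for neutrophil and mast cell, 2 and 3 for stromal, 1 and 0 for endothelial and 1 and 5 for pancreas markers.

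Most of the interferon-responsive genes rose. Of 30 measured members, 20 rose, none fell and 10 did not pass, and adjusted over the list alone 25 rose. Oas2 and Ifi44 were at least 20.8-fold and 18.7-fold higher (adjusted p = 0.000641 and 0.00349). Gbp3, a guanylate-binding protein, rose by 3.05 ± 0.19 and Isg15, the ubiquitin-like interferon product, by 2.90 ± 0.19 (adjusted p = 0.00212 and 0.00218). The median was 1.72, with an adjusted p by camera of 3.38e-17 and an adjusted p of 0.726 with an estimated correlation.

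MHC and antigen presentation genes moved in both directions. Of 24 measured members, 4 rose, 6 fell and 14 did not pass, and adjusted over the list alone 6 rose and 7 fell. All 6 that fell belong to the class II pathway. H2-Aa fell by 2.43 ± 0.19, H2-DMb1 by 2.36 ± 0.19, H2-Ab1 by 1.97 ± 0.20 and H2-Eb1 by 1.73 ± 0.17 (adjusted p from 0.00332 to 0.00613), and H2-DMb2 and H2-DMa also fell. The class II chaperone gene Cd74 had a value of 0.38 ± 0.21 and the class II transactivator gene Ciita of -0.63 ± 0.18 (adjusted p = 0.226 and 0.0665). The class I gene H2-K1 rose by 1.04 ± 0.20, and the peptide-loading genes Tap2 and Tapbp by 1.03 and 1.13. Ctss, a protease that processes the class II invariant chain, rose by 0.87. The list as a whole had a median of 0.04 and a mean of -0.22, and did not pass (adjusted p = 0.914, with a direction opposite in sign to the mean).

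**Figure D2:**
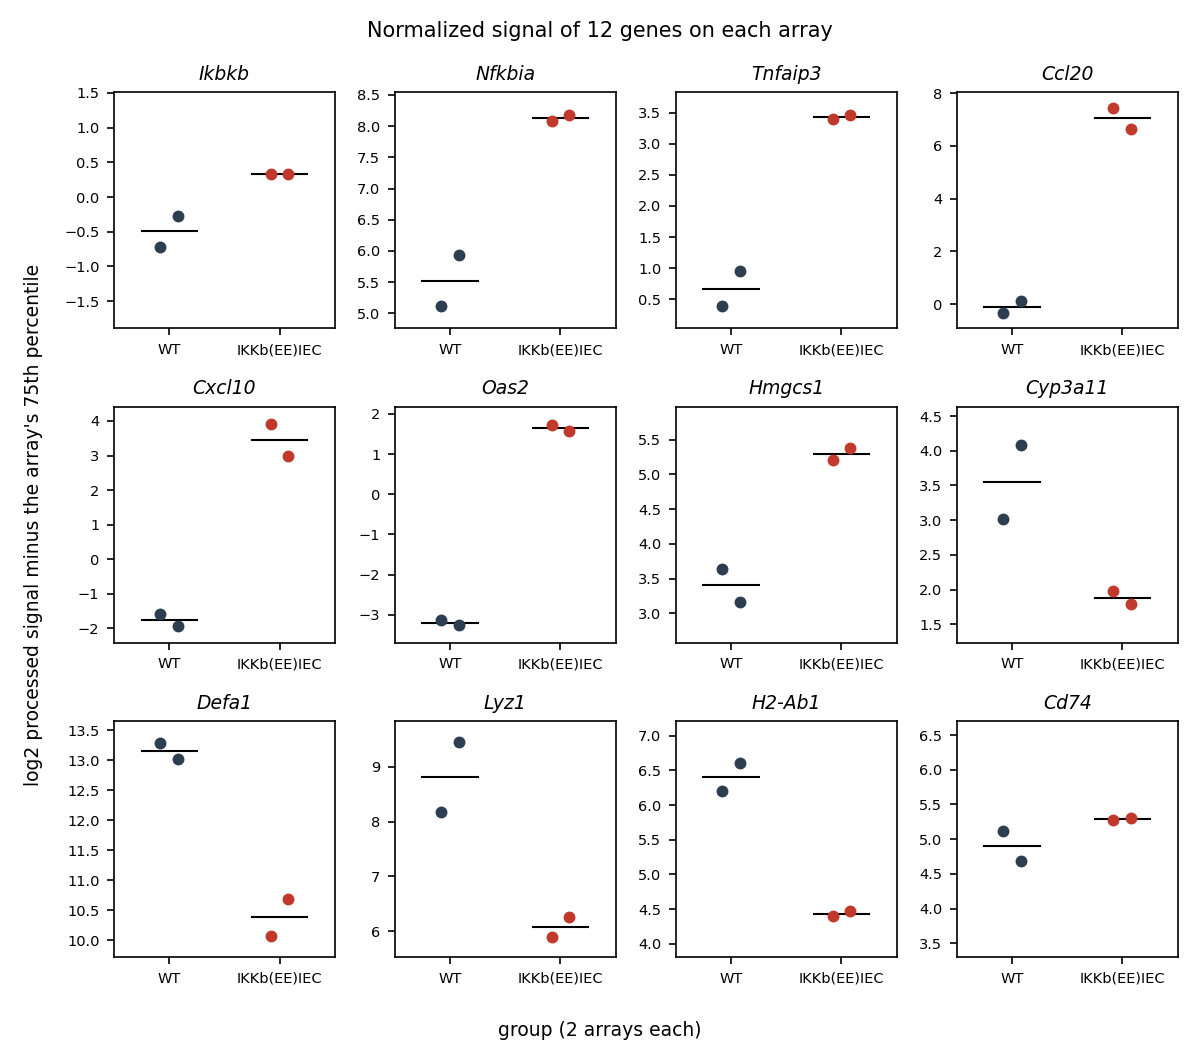
Normalized log2 signal (y axis, with its own range in each panel) of 12 genes on the 2 WT and 2 IKKb(EE)IEC arrays (x axis), with points for arrays, lines for group means and levels that are not comparable between panels. Tnfaip3 lies at 0.39 and 0.95 in WT and 3.39 and 3.47 in IKKb(EE)IEC, while Lyz1 lies at 8.18 and 9.45 in WT and 5.90 and 6.25 in IKKb(EE)IEC.

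Several genes of sterol and fatty acid synthesis rose. Of 24 measured members, 11 rose, none fell and 13 did not pass, and adjusted over the list alone 12 rose and 1 fell. Hmgcs1, which makes the precursor of mevalonate, rose by 1.89 ± 0.22 (adjusted p = 0.00864), Srebf2, the transcription factor of the pathway, by 1.73 ± 0.34 (adjusted p = 0.0332) and Scd2 by 1.99 ± 0.29 (adjusted p = 0.0161). The median was 1.00, with an adjusted p by camera of 9.44e-07 and an adjusted p of 0.726 with an estimated correlation. The fatty acid synthesis members Fasn, Acaca and Elovl6 had values of 1.14 ± 0.44, -0.73 ± 0.21 and -0.27 ± 0.31, none of which passed. Without WT replicate 1 and 2 the values were 1.82 and 0.47 for Fasn and 0.16 and -0.70 for Elovl6.

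More genes of xenobiotic metabolism fell than rose. Of 30 measured members, 10 fell, 3 rose and 17 did not pass, and adjusted over the list alone 14 fell and 4 rose. Aldh1a1, a retinaldehyde dehydrogenase, fell by 1.96 ± 0.18 and Ugt2b5, a glucuronosyltransferase, by 1.79 ± 0.17 (adjusted p = 0.00440 and 0.00506), and the cytochrome gene Cyp3a11 fell by 1.66. In contrast Ahr, the aryl hydrocarbon receptor, rose by 2.56 ± 0.47 and its target Cyp1a1 by 2.59 ± 0.40, with values for Ahr of 3.22 and 1.89 without WT replicate 1 and 2. The median was -0.49, with an adjusted p by camera of 0.0211 and an adjusted p of 0.726 with an estimated correlation, and the list no longer passed with a median shift, without a filter, without IKKb(EE)IEC replicate 2 or with the repaired normexp correction (adjusted p = 0.0807, 0.619, 0.0673 and 0.0638). Among 23 genes of fatty acid oxidation and ketogenesis 5 fell and none rose (median -0.27, adjusted p = 0.342, and 0.0356 with a median shift), with Pdk4 at -2.73 ± 0.42 and Vnn1 at -1.34 ± 0.18 beside Cd36. In the list of NRF2 and oxidative stress genes Mt2 rose by 1.80 ± 0.42, and Gclm and Prdx1 fell by 1.33 ± 0.19 and 1.10 ± 0.22, among 23 (median 0.02, mean -0.03, test upward with adjusted p = 0.893). Proximal small intestine genes had 2 rises, Onecut2 and Adh1, and 1 fall, Ada, among 6 (median -0.16, mean 0.36, test upward with adjusted p = 0.753). Distal small intestine genes had 1 fall, Slc51a, among 10 (adjusted p = 0.254) and passed without WT replicate 1 (median -0.77, adjusted p = 0.0165), while the median was -0.06 without WT replicate 2 (adjusted p = 0.976). Adjusted over the list alone, 0 fatty acid oxidation genes rose and 6 fell, and the corresponding numbers were 0 and 2 for NRF2, 2 and 1 for proximal and 0 and 1 for distal genes.

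Junction and keratin genes were slightly higher as a list, with a median of 0.37 and an adjusted p by camera of 0.0211 (adjusted p = 0.726 with an estimated correlation). Only Cldn23 and F11r of 25 members passed, at 1.02 ± 0.20 and 0.86 ± 0.16, and the list did not pass with a median shift, without WT replicate 2 or without IKKb(EE)IEC replicate 2 (adjusted p = 0.106, 0.0911 and 0.0673). Of 30 apoptosis and survival genes 7 rose and none fell (median 0.13, adjusted p = 0.121), with Ripk3 and Mlkl, which act in necroptosis, at 1.60 ± 0.17 and 1.66 ± 0.23, Cdkn1a at 1.45 and Bcl2l11 at least 3.27-fold higher. The apoptosis list passed without a filter and with the repaired normexp correction (adjusted p = 6.36e-05 and 0.0478). Among 27 immediate early and MAPK-responsive genes 5 rose and none fell (median 0.20, adjusted p = 0.168), led by the growth factor gene Areg at 3.71 ± 0.34 (adjusted p = 0.00448). The heat shock gene Hspa1a was at least 12.2-fold higher, with at least 11.3-fold for a second probe, and Dusp2 and Junb also rose. A further Hspa1a probe showed no change (0.12 ± 0.26, adjusted p = 0.769 in limma over single probes). This list passed without WT replicate 1, with a median shift, without a filter and with the unrepaired normexp correction (adjusted p = 0.00421, 0.0209, 0.00131 and 0.0441). Of 25 ER stress genes Hyou1 alone rose (0.91 ± 0.17), and the list did not pass (median 0.20, adjusted p = 0.0630) but did under 5 of 15 alternatives, among them without WT replicate 2 (adjusted p = 0.00636). Among 14 circadian clock genes Nfil3 alone passed, at -1.41 ± 0.16 (median 0.05, adjusted p = 0.914). Of the sex-linked genes, the X-inactivation transcript Xist was measured on all 4 arrays and was higher in IKKb(EE)IEC by 2.19 (adjusted p = 0.0221), while none of 7 probes for 4 Y-linked genes was well above background on any array. Adjusted over the list alone, 2 junction genes rose and 0 fell, and the corresponding numbers were 7 and 1 for apoptosis, 6 and 2 for immediate early, 0 and 0 for ER stress and 0 and 1 for circadian genes.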

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

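With 2 arrays per genotype and 34.3% to 41.1% of spots well above background, dim genes and changes near 2-fold are the limit of these data. All 105 genes taken by the naming rule separated fully by genotype, so leaving out 1 array could not change their sign. Neither could the replicate block or the trended robust variance, which leave the fold change as it is. None of the 105 genes changed sign under the other alternatives in which they were measured. Of these, 8 no longer passed with quantile normalization (Fabp1, Fabp2, Lct, Ada, Spink4, Prdx1, Slc51a and Mmp9), 8 with a median shift, whose fit gave all genes a common variance (Col4a1, Cr2, Fev, Ltc4s, Myh11, Plk1, Slc51a and Tas1r3), 3 with the percentile over detected probes, 22 with the value table, 102 with normexp as planned, 11 with its repaired form, 36 without a filter and 10 with the replicate block. The counts of 992 higher and 892 lower genes changed as follows. Normexp as planned called 0 and 0 (limma, 77 and 94 at an unadjusted p below 0.05). Its fitted background mean was -104 on WT replicate 1 and -373 on IKKb(EE)IEC replicate 2, where single local backgrounds reached 7724 and 47014, against 41.5 and 45.9 on the other arrays. With the 5 and 4 local backgrounds above 100 set to the array median, an alternative chosen after seeing the data, the counts were 1420 and 552, of which 706 and 530 were also called before. Without a filter they were 501 and 342, with 27727 genes tested. An adjusted p below 0.1 gave 1752 and 2125, and an unadjusted p below 0.05 with a 2-fold change gave 539 lower genes. Leaving out 1 array gave 165 to 2628 higher and 82 to 3534 lower genes; the lone array left in a genotype is assumed to vary like the pair, and the WT pair (SD of the difference 0.523 over genes) varied more than the other (0.262). The settings not named here gave 771 to 1339 higher and 680 to 1157 lower genes.

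The sample titles do not say whether the replicate numbers pair the samples. The WT and IKKb(EE)IEC differences between replicates correlated at 0.108 over genes, which with 2 pairs cannot decide it. With the replicate block, 914 genes were higher and 587 lower, 829 and 551 of them shared with the calls above, and it ended the calls of Col4a1, Cr2, Fev, Junb, Ltc4s, Myh11, Plk1, Slc51a, Tas1r3 and Tpsg1 and changed no call of a list. A slide or scan block was not run, since all arrays share 1 slide.

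Ikbkb passed at 0.87 (adjusted p = 0.0490) with the percentile over detected probes, at 0.88 (0.0417) with a median shift, at 0.83 with the stricter filter (0.0410) and with the trended robust variance (0.0478), and ranged from 0.60 to 1.06 without 1 array. As before, it did not pass at 0.20 with normexp as planned (1.00), 0.31 with its repaired form (0.113) or 0.30 in the value table (0.0989). Nor did it pass with quantile normalization, without a filter, with probe means or with the replicate block. Whether it passed without 1 array depended on the array left out, and such fits leave a single array in 1 genotype. The NF-kB list (medians 0.52 to 1.64) and the Paneth list (-2.71 to -1.60) passed under every alternative at the preset correlation. With an estimated correlation neither did (adjusted p = 0.726 for each), and by fry the Paneth list did not (0.0524). The chemokine list did not pass only with the stricter filter, which removes genes below background in WT (-0.0315, adjusted p = 0.172), and without a filter its median was -0.18 while the test gave a rise. The antimicrobial list passed only without a filter (0.0856, adjusted p = 0.00862), and without 1 array had medians of -0.10 to 0.28. The T and NK cell list passed under none. Of the secondary lists 5 passed, against 8 with normexp as planned, 8 without a filter and 3 to 8 without 1 array. The cause of these other changes was not tested.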

Other observations

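All tests and comparisons in this part were chosen after the results were seen. The 2 WT samples were over 4-fold apart for 76 genes, of which those given here were chosen after their values were seen and stand for no tested theme. WT replicate 2 had more Reg3g (by 3.26 on the log2 scale), Reg3b (2.54), Saa2 (3.29), Ubd (2.97) and Fabp6 (2.95), an ileal bile acid-binding protein. WT replicate 1 had more Duoxa2, Cd55, Retnlb and Gsdmc, with replicate 2 minus replicate 1 at -3.52, -3.36, -3.23 and -2.66. The IKKb(EE)IEC samples differed by -0.09 for Reg3g, -0.09 for Retnlb and 1.22 for Fabp6. Tuft cell markers had a median of -1.22 (replicate 2 minus replicate 1) in WT and -0.05 in IKKb(EE)IEC, and distal small intestine genes of 0.81 and 0.22. Of 5 liver transcripts looked at, 4 (Alb, Ahsg, Fgb and Apoh) were well above background on WT replicate 2 only, and Ttr on no array.

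Probes of a gene did not always move together. Of 96 genes with over 1 probe and a probe past the test by over 4-fold, 33 (34.4%) had another measured probe within 0.75 log2 units of 0. This counts against reading single-probe steps as changes of the whole gene without a further probe. Such steps include the falls of Farsa and Zfp423 and the rises of Csf1, Tnfrsf13c, Xlr5a, Rps6kl1 and Epop.

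For the fall of 10 of 11 Paneth markers, a lower yield of crypt bases is argued against only as the whole cause. The stem cell and Wnt target list had a median of -0.11 (SD 0.68 over members) and the cell cycle list of 0.12, against -2.55. The first of these mixes stem cell with Wnt target genes, and its members moved both ways. Lgr5 and Olfm4 were at -0.23 and -0.45, Sp5 at -1.26 and Cd44 at 1.83, so a partial loss of crypt bases stays open. A more proximal stretch of intestine in the IKKb(EE)IEC samples stays open. The distal list had a median of -0.41, with 8 of 10 members lower, and it rests on single arrays (-0.77 and -0.06 without WT replicate 1 and 2). This lies between limits of -1 and 0 that were set after the values were seen. No sample of known position shows what shift a more proximal stretch would give. Fewer Paneth cells, or less of these transcripts per cell, with constant IKKb activity may be the biological reading, and stays a hypothesis.

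The rise of macrophage markers was not shared by the lists of T and NK cell, stromal and B cell markers. The T and NK cell list had a median of -0.22 (SD 0.43 over 22 members), against 1.20. The value of 1.20 includes 7 of 19 members with only a bound, against 0 in the T and NK cell list. Over members well above background on all arrays the macrophage median was 0.10, and that list did not pass. The stromal and muscle list had a median of -0.26, the B and plasma cell list of -0.12 and the neutrophil and mast cell list of -0.53. The endothelial and blood list had a median of 0.15, with Pf4 higher. A lower share of epithelial cells is not excluded by this, since the T and NK cell list includes intraepithelial cells, which lie within the epithelium. More mononuclear phagocytes among the isolated cells cannot be told apart from expression of such genes in the epithelium: of C1qa, C1qb, C1qc and Csf1r, 2 were higher by at least 1 log2 unit, and C1qb was at -0.15. The C1qb signal in WT was already well above background, so a small share of such cells could be hidden in it.

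The class II genes fell while interferon-responsive genes rose, and 6 class II genes had a median of -1.85. Fewer professional antigen-presenting cells would lower Cd74 with them, unless other cells made more of it. Cd74 was at 0.38 (SE 0.21, with 0.59 and 0.17 without WT replicate 1 and 2). The values do not tell which cells a transcript came from, so Cd74 cannot decide this, and fewer such cells stay open as a cause. A variant under single probes is argued against for H2-Aa and H2-Ab1, of whose 6 probes the one with the smallest fall was at -1.94. A difference of MHC haplotype between the genotypes, an effect of position on the slide and lower class II transcription in the epithelium of IKKb(EE)IEC mice stay open and were not tested.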
